A study of Mus musculus with 2 samples.

How the data were processed

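RNA was measured in regulatory T cells (Treg), the CD4 T cell subset that restrains immune responses and depends on the transcription factor Foxp3. The cells were sorted by flow cytometry from spleen and lymph nodes of female mice aged 6 to 8 weeks, per the labels. Both donors carried a Cre recombinase at 1 of their Foxp3 alleles. They differed in the gene for the transcription factor Stat3: 1 donor genotype had a single loxP-flanked (floxed) Stat3 allele (fl/wt) and the other had both alleles floxed (fl/fl), so that Cre removes Stat3 exons from 1 or from both copies. Foxp3 lies on the X chromosome, so in such females Cre is active only in Treg that use the Cre-bearing X. The labels do not say whether the sort selected those cells, how many mice gave each sample, or which Stat3 exons are floxed.

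Total RNA was taken up in Trizol and biotin-labelled cRNA was hybridised to Affymetrix arrays, per the labels' protocols. The deposited table holds log2 values of 45101 probe sets for 2 arrays, 1 per genotype. GCRMA is named in the submitters' processing notes as the method behind these values. Its version and settings, and whether further arrays were normalised together with these 2, are not given in the sources used here. GCRMA subtracts a background estimated from probe sequence and normalises the arrays to each other, which pulls dim probe sets to a dense low end with no order among them. The log2 scale was read from the deposited values, which ran from 0.53 to 16.9 with medians of 3.47 (fl/wt) and 3.50 (fl/fl). Values before normalisation were not used here.

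Probe sets were named from the platform annotation given with the data. Of the probe sets, 34958 were paired with 1 gene symbol and 932 with several, and 9160 that are not controls had none. There were 64 control probe sets. Some of these carry a gene symbol, such as that of Gapdh, and are counted among the named ones. Symbols were looked up by Entrez identifier in the RefSeq table of GRCm38.p6; 34754 named probe sets matched and none changed its symbol. Only probe sets with 1 symbol were used for genes. No genome build is named for these values, so no coordinates are given.

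Differences are log2 values of the fl/fl array minus the fl/wt array. A gene was represented by its probe set with the highest mean over both arrays. Genes at or above log2 5 in at least 1 array were kept, and a value under 5 was set to 5, so that a difference against it is a lower bound. Where other measured probe sets of a named gene differ in direction, the text says so. With 1 array per genotype there is no replicate error, and no p-value, standard error or adjusted p is given. The number of arrays limits the precision. As a description of these 2 arrays, each gene over log2 5 in both was set beside the 500 such genes nearest in level. The central 95% of their differences is quoted for some genes only. For gene lists, the median difference was ranked as a percentile among 10000 random lists of the same size matched on mean level in 20 bins. A list stands apart below percentile 2.5 or above 97.5. The 28 lists, the rule for named genes and the alternatives were fixed before the data were examined, except where the text says otherwise. Lists with fewer than 4 measured members have values only.

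The rule named, among genes at or above log2 5 in both arrays, the 10 with the largest positive and the 10 with the largest negative difference. A gene was passed over if another of its measured probe sets went the opposite way, and unannotated clones and antigen receptor segments were left out. For genes at that level in 1 array only, the 5 largest lower bounds in each direction were named by the same rule. Members of the Treg identity, suppressor, Th17, Stat3-linked and trafficking lists could also be named, and up to 4 members of each other list. Of the 438 listed genes, 48 had no probe set of a single gene here, 56 were under log2 5 in both arrays and 334 were measured.

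Added after the data were seen was a comparison of pairs of probe sets that read the same gene. For each gene with at least 2 probe sets of the plain type (no suffix that marks shared probes) at or above log2 5 in both arrays, the differences of its 2 brightest probe sets were correlated over genes. Intervals come from 1000 bootstrap draws of genes, and the range without any pairing from 1000 shuffles of partners within bins of level.

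The procedures were tested on simulated data with the real levels and the real spread, where changed genes were drawn from those with a mean at or above log2 7. All 100 genes raised by 1.5 and all 100 genes lowered by 2 on the log2 scale passed 2-fold, against 4 of 9567 unchanged genes. A list of 20 genes shifted by 0.1 reached percentile 100, and 4 of 100 unshifted lists of 15 genes stood apart. The gene shifts exceeded the 2-fold threshold, and the list shift exceeded every list median found in these data. Smaller effects, and changed genes under log2 7, were not simulated. Alternatives were floors of 6 and 4, no floor, 32 added on the linear scale, the median over a gene's probe sets, probe sets of shared suffix left out, 3 other scalings between the arrays, 2 other fold thresholds, unmatched random lists, and the mean of a list. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6 were used.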

Results

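Expression profiles of Treg from 2 Stat3 genotypes were compared to ask which transcripts depend on Stat3, the transcription factor downstream of IL-6, IL-10 and related cytokines. The data were 1 array from fl/fl Treg and 1 array from fl/wt Treg, named below by their labels. With no replicates, no difference below has a replicate check. Of 45101 probe sets, 19393 were at or above log2 5 in both arrays. At gene level, 9669 genes reached log2 5 in both arrays, 57 only in the array labelled fl/fl and 48 only in the array labelled fl/wt. Ctla4, an inhibitory receptor of Treg, stood at log2 14.91 (fl/wt) and 14.87 (fl/fl), and Ikzf2, which encodes the Treg factor Helios, at 13.88 and 13.86. The Foxp3 probe set was under log2 5 in both, at 4.09 (fl/wt) and 3.52 (fl/fl), where values have no order.

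Stat3 had 3 probe sets above log2 5, and none was lower in the array labelled fl/fl by more than 0.083 on the log2 scale. The brightest read 11.99 in fl/fl, a difference of -0.0083 from fl/wt. The next differed by -0.019 (10.65 in fl/wt and 10.63 in fl/fl) and the third by -0.083 (10.45 and 10.37). The last of the 4 Stat3 probe sets lay under log2 5 in both arrays, at 2.26 and 2.36. Where these probe sets lie relative to the floxed exons is not given in the sources used here. A probe set outside the deleted exons does not read the deletion, so these values do not check the labels, and directions below rest on the labels alone.

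The 2 arrays were nearly equal across the transcriptome. Of the 9774 genes at or above log2 5 in at least 1 array, 73.2% differed by less than 0.1 and 94.2% by less than 0.25 on the log2 scale. The correlation across all probe sets was r = 0.9993, taken over probe sets, which are not independent replicates. A difference of at least 2-fold was seen for 3 genes higher and 2 genes lower in fl/fl, and of at least 1.5-fold for 24 higher and 39 lower. The 2-fold counts depend on the floor: with a floor of log2 4 they were 9 and 6, and with 32 added on the linear scale 0 and 0. Higher were Ccnk, Gcfc2 and the receptor segment Trav12n-2, and lower were Chchd5 and Traip. Trav12n-2 was under log2 5 in fl/wt (4.44), so its difference of 1.12 is a lower bound, which was 0.12 with a floor of log2 6 and 1.68 with a floor of 4. Trav12n-2 and Chchd5 fall outside the naming rule and were chosen after their values were seen. A second probe set of Chchd5 went the opposite way, by 0.32, and the other 4 genes had no second measured probe set.

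The genes with the largest differences were mostly dim. Ccnk, a cyclin that works with transcriptional kinases, read 6.84 in fl/wt and 8.02 in fl/fl, a difference of 1.18. Gcfc2 differed by 1.01, Mrap, an accessory protein of melanocortin receptors, by 0.96, Nckap5l by 0.89 and the S-phase cyclin Ccne2 by 0.84. Gnptg (0.77), Klhl8 (0.76), Acvr1c (0.74), Zc3h3 (0.68) and Acyp2 (0.66) completed the 10 highest. On the lower side, the ubiquitin ligase Traip differed by -1.03, the phospholipase Pla2g4f by -0.93, Dennd2c by -0.90, Lypd6b by -0.87 and the transcription factor Bcl11a by -0.86. The erythropoietin receptor Epor followed with -0.86, then Mettl27 (-0.84), Epop (-0.82), the fucosyltransferase Fut7 (-0.79), which builds selectin ligands, and Lamc1 (-0.77). None of these 20 genes had a second measured probe set. With a floor of log2 6 the difference was 0.66 for Gcfc2, 0.065 for Zc3h3, -0.53 for Traip, -0.34 for Dennd2c, -0.26 for Epop, -0.066 for Fut7 and -0.10 for Lamc1. As the median over all probe sets, dim ones included, it was 0.48 for Mrap and 0.39 for Klhl8. With 32 added on the linear scale it was 0.42 for Acvr1c, -0.50 for Bcl11a and -0.50 for Mettl27. For the 500 genes nearest to Ccnk in level the central 95% of differences ran from -0.43 to 0.38, and for those nearest to Traip from -0.66 to 0.50. Among genes over log2 5 in 1 array only, Mocs1 was at least 1.85-fold higher, Aspa 1.69-fold, Ifit1bl2 1.53-fold, Brip1 1.47-fold and Nhlrc1 1.35-fold. The protease Ctsf was at least 1.94-fold lower, Npl 1.85-fold, Daw1 1.64-fold, Prf1 1.54-fold and Tango6 1.52-fold. For the genes nearest to Acvr1c, at a like level, the central 95% of differences ran from -0.67 to 0.49. The log2 bounds of Nhlrc1 (0.43), Prf1 (-0.63) and Tango6 (-0.60) lie inside that range, which comes from genes over log2 5 in both arrays. As lower bounds they do not show that the differences themselves lie inside it. These sizes depend on the floor: with a floor of log2 4 the difference was 1.81 for Mocs1, 1.22 for Brip1, 0.70 for Nhlrc1 and -1.27 for Ctsf.

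**Figure D1:**
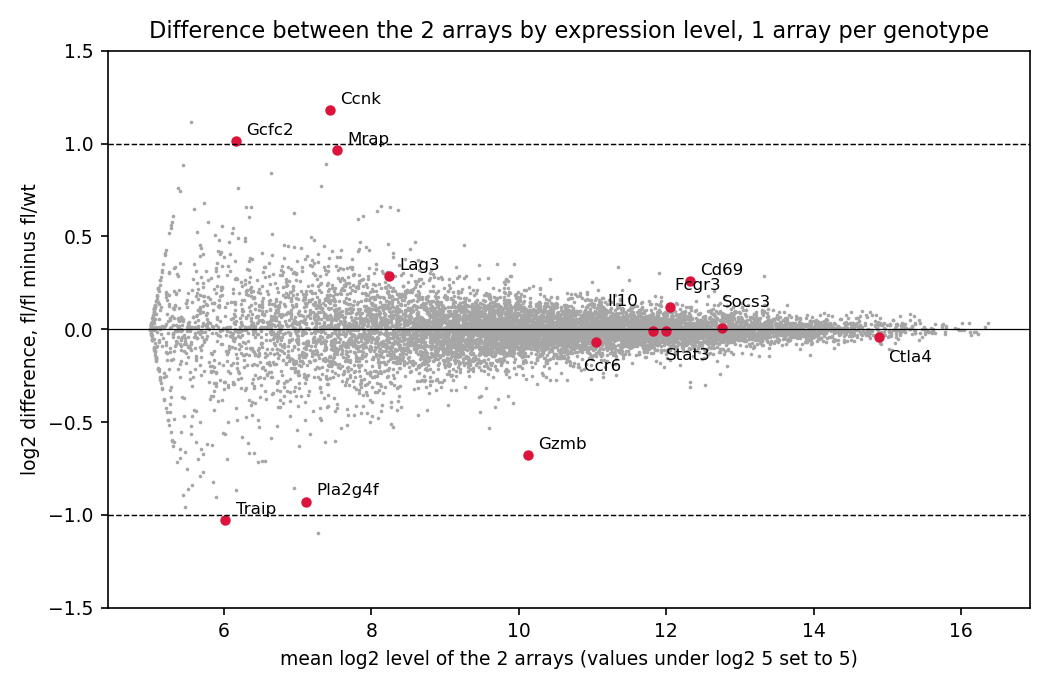
Log2 difference between the array labelled fl/fl and the array labelled fl/wt (y axis) against the mean log2 level of the 2 arrays (x axis), 1 point per gene, with values under log2 5 set to 5. Red points are labelled genes, all from the text except Fcgr3 of the myeloid list, and dashed lines mark 2-fold. The spread narrows as the level rises, Stat3 lies at -0.0083 and Gzmb at -0.68.

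Genes of Treg identity differed by -0.10 to 0.096 on the log2 scale. Of 19 measured members, 8 were higher and 11 lower in fl/fl, none by 1.5-fold, and the list median was -0.0060 (percentile 44.7 among random lists). The IL-2 receptor chain Il2ra differed by -0.10 and Ctla4 by -0.043. Ikzf4, which encodes the factor Eos, differed by 0.096 and its other probe set by -0.14. Ikzf2 differed by -0.025 and its other probe set by 0.049.

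Among molecules that Treg use for suppression, the cytotoxic effectors Gzmb and Prf1 had the largest differences, both lower in fl/fl. Gzmb, the protease granzyme B, read 10.46 in fl/wt and 9.78 in fl/fl, a difference of -0.68. None of the 500 genes nearest to it in level differed as much, and their central 95% ran from -0.17 to 0.15. Ccnk, Acyp2 and Traip likewise had no such neighbour, and in any pair of arrays some genes come first in this way. Prf1, which encodes perforin, was at 5.63 in fl/wt and under log2 5 in fl/fl (4.81), a bound of -0.63. For genes of about that level, those nearest to Acvr1c, the central 95% ran from -0.67 to 0.49. As a lower bound, -0.63 does not show whether the Prf1 difference lies inside that range. Gzmb and Prf1 were each read by a single measured probe set. The inhibitory receptor Lag3 differed by 0.29, inside the central 95% of its neighbours in level (-0.34 to 0.31). The anti-inflammatory cytokine Il10 differed by -0.0074, Ebi3, a subunit of IL-35, by 0.014 and Gzma by -0.012. Over the 16 measured members, 4 were higher and 12 lower, with a median of -0.011 (percentile 34.6). The mean, which the pair of cytotoxic genes can move, was -0.076 and stood apart (percentile 2.26).

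Genes linked to Stat3 did not stand apart. Of 20 measured members, 8 were higher and 12 lower in fl/fl, none by 1.5-fold, with a median of -0.021 (percentile 16.4). Without probe sets of shared suffix the median was -0.0016 (percentile 56.1). Socs3, a feedback inhibitor induced through Stat3, differed by 0.0063 and Bcl3 by 0.070. The largest differences were -0.29 for the AP-1 factor Fosl2 and -0.17 for Ier3. Of the 9 measured Th17 genes, 5 were higher and 4 lower with a median of 0.026 (percentile 85.5). These included the chemokine receptor Ccr6 (-0.069), the IL-6 receptor Il6ra (0.10) and Batf (0.055). Il17a, Il21 and Il1r1 were under log2 5 in both arrays. Janus kinases, Stat proteins and cytokine receptors had 8 members higher and 14 lower, with a median of -0.023 (percentile 13.9). Stat2 (0.21) and Ifnar1 (-0.17) differed most, and the other probe set of Ifnar1 went the opposite way.

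The list of IL-2 and Stat5 responsive genes was the only one of 24 lists whose median stood apart. Its 14 measured members had a median of -0.061 (percentile 0.08), with 3 higher and 11 lower in fl/fl. Gzmb and Prf1 belong to it, and Cish, a Stat5-induced inhibitor of cytokine signalling, differed by -0.12. Socs1, a further such inhibitor, was at 5.11 in fl/wt and under log2 5 in fl/fl. Among 24 lists, 1.2 are expected to stand apart with no effect at all, counted at the percentile cuts that define standing apart. Lists share members such as Gzmb, so they are not independent draws. The IL-2 and Stat5 list, at percentile 0.08, lay well beyond the lower cut, and the number of lists expected at that depth was not computed. The list no longer stood apart when a gene was read as the median of its probe sets (-0.029, percentile 12.9) or when probe sets with shared suffixes were left out (-0.029, percentile 8.99). It stood apart with both other floors, no floor, 32 added, the 3 other scalings, unmatched random lists and the mean, at percentiles of 0.05 to 1.19.

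Homing molecules had 8 members higher and 11 lower, with a median of -0.0083 (percentile 40.3). The chemokine receptors Cxcr4 (0.16), Ccr10 (0.15) and Cxcr5 (-0.14) differed most. Helper lineage lists were also within their random ranges. The Th1 list had 2 members higher and 8 lower, with a median of -0.041 and Runx3 at -0.20. The Th2 list had 3 higher and 3 lower, with a median of -0.0046 and Gata3 at -0.071. The follicular helper list had 7 higher and 3 lower, with a median of 0.020. Genes of naive or central T cells had 4 higher and 9 lower, with a median of -0.0095. Effector Treg genes had 8 higher and 13 lower, with a median of -0.014 (percentile 25.1). Gzmb (-0.68) and Anxa1 (-0.33) differed most among them, and their mean of -0.054 stood apart (percentile 0.34).

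Of the S-phase and mitosis genes, 13 were higher and 16 lower, with a median of -0.030 (percentile 4.67). Cenpe (-0.37), Tpx2 (-0.31) and Kif20a (-0.24) were on the lower side and Aurka (0.31) on the higher. Without probe sets of shared suffix the median was 0.021, and the mean of the list was -0.051 and stood apart (percentile 1.60). Interferon-induced genes had 9 higher and 12 lower, with a median of -0.0043, Mx1 at 0.31 and Oasl1 at -0.18. In the Bcl2 family and death list, 7 were higher and 8 lower, with a median of -0.0035. Its pro-apoptotic member Bak1 differed by 0.66, with 1 of the 500 genes nearest in level at least as far apart, but by 0.078 as the median over its probe sets, dim ones included. The death receptor Fas differed by 0.27 and its ligand Fasl by -0.22. Not every list median kept its direction: 10 of the 24 lists had a value of opposite sign under at least 1 alternative, none of which stood apart. Medians of glycolytic enzymes (0.011), respiratory chain subunits (-0.017), ribosomal proteins (-0.0080) and T cell receptor signalling genes (-0.00018) lay within their random ranges.

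**Figure D2:**
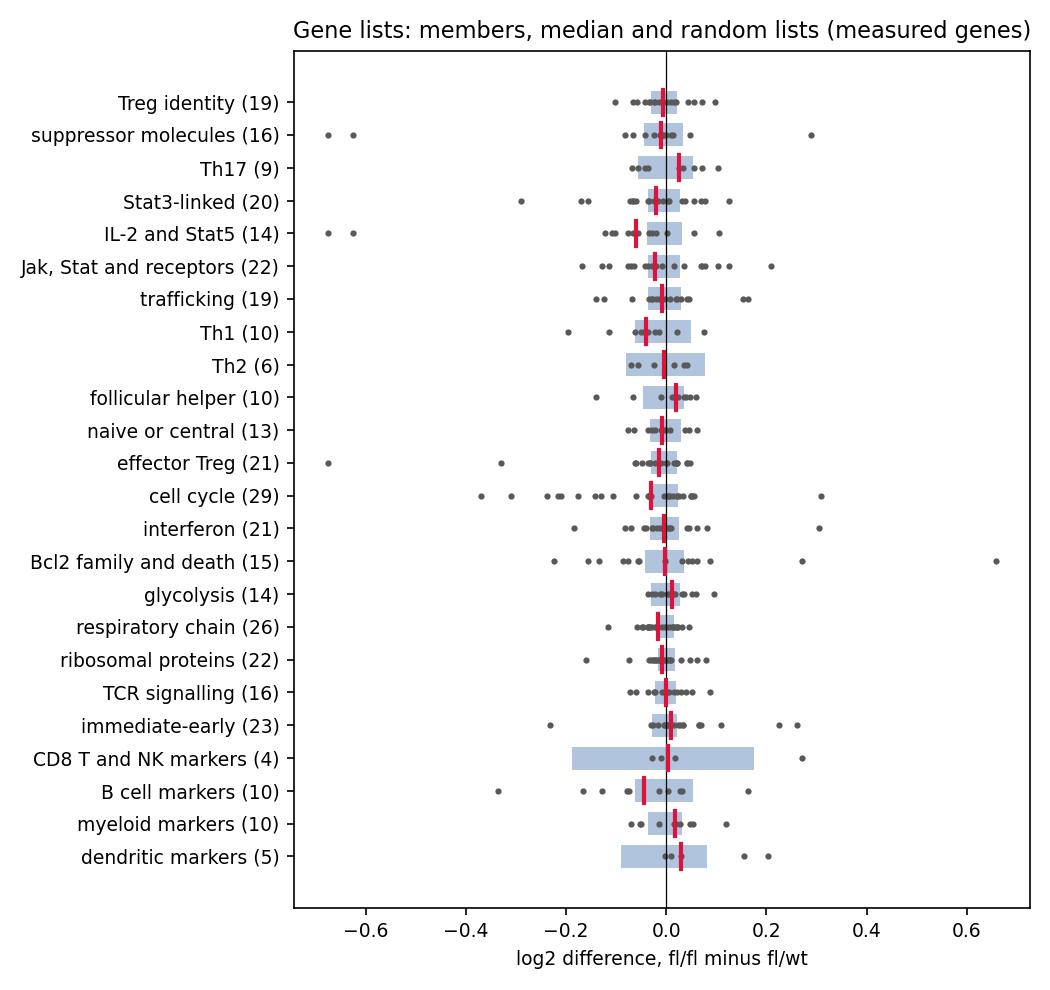
Log2 difference between the fl/fl and fl/wt arrays (x axis) for the 24 gene lists with at least 4 measured genes (y axis, number measured in parentheses). Dark points are genes, with genes under log2 5 in 1 array at their lower bound, red bars are list medians and blue bars hold the central 95% of medians of 10000 random lists of like level; only the median of the IL-2 and Stat5 list, at -0.061, lies outside its blue bar.

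Some markers of other cells were at or above log2 5 in both arrays, and none of their lists with a percentile stood apart. Myeloid markers had 6 members higher and 4 lower, with a median of 0.017 (percentile 87.3). Among them, the lysozyme gene Lyz2 read 12.59 in fl/wt and 12.52 in fl/fl, and Adgre1, the macrophage antigen F4/80, 12.04 and 12.09. B cell markers had 4 higher and 6 lower, with a median of -0.045 (percentile 7.27). This B cell median depends on the floor: it was -0.014 (percentile 34.2) with a floor of log2 6, 0.0042 (37.8) with no filter and no floor and 0.0012 (41.1) with 32 added on the linear scale. Ms4a1, which encodes CD20, read 7.48 and 7.15, while its other probe set differed by 0.28. Levels in this list varied widely: Blk read 5.31 in fl/wt and 5.15 in fl/fl, Cd79b 10.34 and 10.26, and Cd74 13.55 in both arrays. CD8 and NK markers had a median of 0.0036 with Cd8b1 at 0.27, and dendritic markers a median of 0.030 with Itgax at 0.20. Of the plasma cell genes, Ighm read 13.98 in fl/wt and differed by -0.012, with its other probe sets not all in that direction. Jchain read 10.03 in fl/wt and differed by 0.047. The red cell gene Alas2 differed by -0.28, the platelet gene Pf4 by 0.20 and the endothelial gene Pecam1 by 0.083. Immediate-early and heat shock genes, which respond to cell handling, had 16 higher and 7 lower, with a median of 0.0096 and Cd69 at 0.26. The 3 probe sets of Xist, transcribed from the inactive X, differed by 0.0027, 0.054 and, for the dimmest, -0.63. The Y-linked genes Eif2s3y, Kdm5d and Uty were under log2 5 in both arrays of these female mice. As a sign of RNA quality, 3' minus 5' control signal was 1.83 (fl/wt) and 1.86 (fl/fl) for Actb and 1.87 and 1.89 for Gapdh.

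The differences of probe sets that read the same gene were uncorrelated over all pairs. Over 2509 genes with at least 2 such probe sets, the correlation of their differences was r = -0.0031, with a bootstrap interval of -0.050 to 0.046. Shuffled partners gave -0.046 to 0.045. Genes are not independent replicates, and this interval describes the 2 arrays only. The direction matched in 49.8% of the pairs, and no pair had both probe sets past 1.5-fold. Of the 23 pairs with either probe set past 1.5-fold, 16 matched in direction, at the upper edge of the 7 to 16 that shuffled partners gave. In these pairs the larger difference had a median size of 0.71 and the smaller of 0.089. Of 11 probe sets past 2-fold at or above log2 5 in both arrays, 8 had other measured probe sets of their gene, and the largest difference among these others was 0.32 in size. Igfbp4, chosen after its values were seen, had 1 probe set at 1.09 and 4 others from -0.047 to 0.11.

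**Figure D3:**
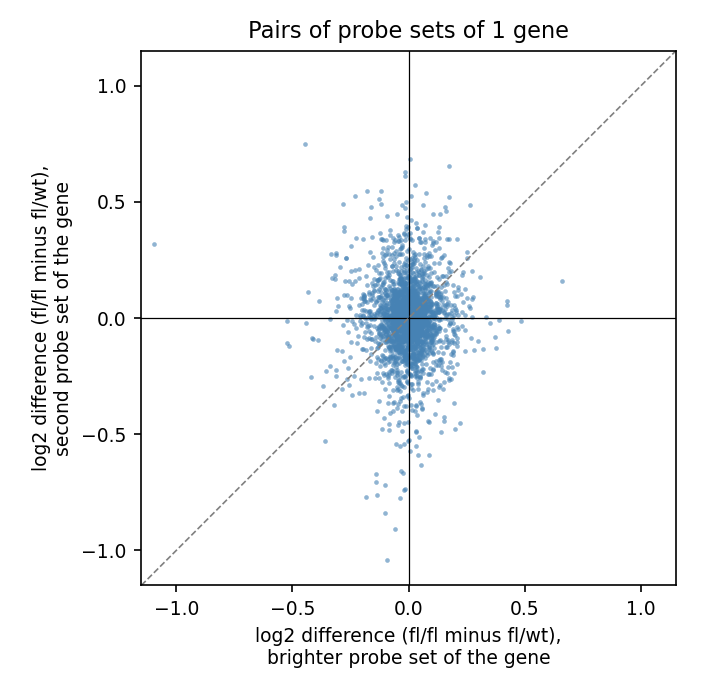
Log2 difference between the fl/fl and fl/wt arrays for the brighter probe set of a gene (x axis) against that of its second probe set (y axis), 1 point for each of 2509 genes, with the line of equality dashed. The points do not follow the line (r = -0.0031).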

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

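The probe set pair correlation with its 8 alternatives and the list without Gzmb and Prf1 were chosen after the data were seen; the other alternatives were planned. The counts of genes past 2-fold (3 higher and 2 lower) were 1 and 1 with a floor of log2 6, 9 and 6 with a floor of 4, and 16 and 9 with no filter or floor. They were 0 and 0 with 32 added on the linear scale, 4 and 0 with the median of probe sets, and 3 and 1 without shared-suffix probe sets. A 1.5-fold threshold gave 24 and 39 and a 3-fold one 0 and 0, by construction. Centring, quantile normalisation and loess gave 3 and 2, and moved the median of all genes by at most 0.0035. The Stat3 difference ran from -0.051 to -0.0034 over 9 alternatives. List values moved beyond a tolerance set from the width of the random range in 4 cases and stayed within it in 258. The cell cycle median was 0.021 without shared-suffix probe sets; the cause was not tested. The mean, which single members can move, was -0.076 for suppressor molecules, -0.13 for IL-2 and Stat5 genes and -0.054 for effector Treg genes. Median and mean differed in sign for the interferon, Bcl2 and T cell receptor lists. Over all alternatives 10 of 24 lists had a value of opposite sign, none of which stood apart, and 23 had a value of opposite sign or more than 1.5 times apart. Among others, signs changed with no filter or floor for B cell (0.0042) and Th2 (0.015) lists, without shared suffixes for cell cycle (0.021), glycolysis (-0.0055) and Bcl2 (0.0046) lists, as the median of probe sets for Bcl2 (0.018), interferon (0.0020), ribosomal (0.0011) and T cell receptor (0.0016) lists, with quantile normalisation for Treg identity (0.0028) and with loess for CD8 and NK markers (-0.0067). Of the 30 genes named by rank, 17 had a value with a floor of 6, 22 as the median of probe sets and 24 without shared suffixes; no value run for them changed sign, and 42 moved by more than 0.19, the SD between probe sets of 1 gene, against 201 that did not. Of values for 55 other genes of the text, 9 moved and 470 did not, and 4 genes changed sign as the median of probe sets: Ikzf4 (-0.14), Ikzf2 (0.049), Csf1r (-0.055) and Igfbp4 (0.54). The correlation of pairs ran from -0.037 to -0.0016. Dim signal limits what can be seen, with an SD of differences of 0.25 at log2 5 to 6 and 0.039 at 14 to 15. No paired analysis was possible because each genotype has 1 array.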

Other observations

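All tests in this part were chosen after the values were seen. Transcripts typical of splenic red pulp macrophages, which recycle iron from old red cells, were at high level in both Treg arrays. A list of 15 such markers was written after values were seen, and 2 of its genes are also in the myeloid list. Slc40a1, the iron exporter ferroportin, read 14.04 in fl/wt and 14.07 in fl/fl, and the adhesion molecule Vcam1 14.87 and 14.86. Csf1r, the receptor for macrophage colony-stimulating factor, read 13.99 in fl/wt and differed by 0.015, with its other probe sets at -0.055 and -0.058. The complement gene C1qa read 13.83 in both arrays, Cd5l 13.33 and 13.27, and Spic, a transcription factor of these macrophages, 12.31 and 12.22. The granulocyte genes S100a8, S100a9, Ngp and Ltf and the collagen genes Col1a1 and Col3a1 were under log2 5 in both arrays.

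A difference in macrophage RNA between the arrays is argued against, since the median over the 15 markers was 0.0023 on the log2 scale and the largest marker difference was 0.088. Macrophage RNA in the sorted cells is a candidate explanation for the level itself: 100% of the markers were at or above log2 5 in both arrays. It cannot be told apart from expression by the Treg, because the markers were picked after values were seen and which of them Treg express was not tested. The labels give no gate, and a sort of Treg should remove macrophages. Such RNA would bring Stat3 transcripts that a Foxp3-driven Cre leaves intact, in an amount not tested here.

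The arrays were nearly identical although their labels name 2 genotypes. A broad RNA difference hidden by noise is argued against by the upper bound of r between probe sets of 1 gene, 0.046, which corresponds to a shared difference with an SD of at most 0.028 on the log2 scale if both probe sets respond alike. The value itself, r = -0.0031, is what the same RNA on both arrays, or RNA alike to within this bound, would give, though 16 of the 23 pairs with a difference past 1.5-fold matched in direction, at the edge of the shuffled range of 7 to 16, and 1 of 45101 probe sets had an identical value, so neither column is a copy of the other. Whether the upstream normalisation flattened real differences cannot be told apart from this (r = -0.0048 after a further quantile normalisation), because values before it were not used here. An effect of genotype on a few genes, such as Gzmb with its single measured probe set, and a deletion that the Stat3 probe sets do not read stay open. Also open is a genotype effect diluted by the design. Treg that use the X without Cre keep Stat3, and the labels do not say whether they were sorted out. The fl/wt Treg with active Cre themselves lose 1 copy. How far this lessens a difference was not tested.

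The lower median of the IL-2 and Stat5 list did not rest on Gzmb and Prf1 alone, since without them it was -0.046 (percentile 0.86). Whether it comes from the spread of single probe sets cannot be told apart from a shift of the genes. Other probe sets, measured for 6 members, had a median of -0.029 (percentile 19.1), but the central 95% of random sets ran from -0.061 to 0.050 and would also hold the -0.046 of the main probe sets of these 6 genes. An effect of the genotype stays open and was not tested, with 1 array per genotype.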
